A study of Mus musculus with 40 samples.

How the data were processed

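The series holds ChIP-seq of small pre-B cells sorted from mouse bone marrow, with 40 samples: 36 ChIP libraries (2 replicates per target and condition, biological per the labels) and 4 inputs. The targets were CTCF, NIPBL, RAD21, SMC3, WAPL, H3K27ac and H3K4me1 in wild type (WT) and Brwd1 knockout (KO) cells, and the first group of cohesin proteins (NIPBL, RAD21, SMC3 and WAPL) also in WT cells given oligomycin (ATPneg). Samples were grouped by their titles, and the WT samples of H3K27ac and H3K4me1, whose titles name no genotype, by their descriptions. For the KO libraries of H3K27ac and H3K4me1 the genotype label reads WT while the title and description say knockout, and the titles were followed. The peak names inside some lists belong to other samples: the H3K27ac KO lists hold H3K4me1 names, the H3K4me1 WT lists hold H3K27ac knockout names, and NIPBL KO 2 and NIPBL WT 1 hold names of the other genotype.

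Per the submitters' processing notes the build is mm9 and the tools were BWA, Picard, MACS2, bedtools, featureCounts and edgeR; no versions are given. The deposited counts are reads per merged region of a target for each ChIP library and for 1 input column per genotype. The counts of H3K27ac and H3K4me1 come without these genotype input columns. The authors' input-subtracted counts are a score per region and library, from which the input was taken. In the deposited normalized signal each column equals the input-subtracted counts times 1 constant, as checked from the values; how the constant was chosen is not stated, and the signal was not used in a test. The deposited peak lists give coordinates and a peak score for each library, and the deposited merged regions give other coordinates without values. The KO and WT libraries have counts, and the ATPneg libraries have peak lists without counts. The files hold 2 per-sample columns of external inputs that were not used here.

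Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr, quasi-likelihood F tests and Benjamini-Hochberg adjusted p under 0.05, with 2 KO against 2 WT libraries. Group values are mean CPM with TMM factors, log2 fold changes carry their standard error, and a region is assigned to the nearest gene within 200 kb. The merged regions numbered 81440 for CTCF, 61724 for NIPBL, 88793 for RAD21, 83467 for SMC3, 127769 for WAPL, 240561 for H3K27ac and 180017 for H3K4me1. Sets were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated one. Region classes were WT consensus peaks of another target (17 tests). Gene lists were tested on counts summed per gene, with 84 tests adjusted together. The lists, with their sizes, were B lineage transcription factors (27), T cell (22), cohesin, CTCF and BRWD1 (26), erythroid and megakaryocyte (23), glycolysis and energy stress (31), housekeeping (20), late and mature B cell (30), mitochondrial oxidative phosphorylation (32), myeloid (27), pre-B receptor and Ig recombination (23) and proliferation and early pro-B (31), plus the Igk window at 67 to 71 Mb of chromosome 6.

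Peak lists were compared with bedtools 2.31.1 at an overlap of at least 1 bp. A consensus peak is a replicate 1 peak that overlaps a replicate 2 peak, and a cohesin site is a RAD21 consensus peak that overlaps an SMC3 consensus peak. Shares carry exact binomial 95% intervals, which treat the peaks of a list as independent and leave out the spread between libraries. Overlap by position alone was measured after a shift of the peaks by 1 Mb. Because ATPneg libraries have no counts, the planned edgeR tests with ATPneg and the correlation of its fold changes with those of KO were replaced by peak overlaps. The planned edgeR test of the input was not run, since 1 column per genotype leaves no replicates; input ratios use regions with at least 20 reads. Other computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

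The comparisons, tests, gene lists, the rule for named regions and a first set of alternatives were chosen before the data were examined. The rule takes, among called regions with mean log2 CPM at or above the median of the tested regions and groups that do not overlap, the first 6 higher and 6 lower by absolute log2 fold change with distinct symbols, passing over predicted, microRNA, olfactory, vomeronasal and Riken symbols. It adds up to 2 genes per list by adjusted p, Brwd1, Igll1, Rag1, Myc and Cd74, and regions of the Igk window, and the text prints a part of these. Alternatives were library totals, background scaling (the 25% of regions with the lowest mean CPM), DESeq2 1.42.0, no filter beyond 1 read, input-subtracted counts, a replicate block, each library left out, a stricter score of 2 times the lowest, an overlap of 50% and the union of replicates. Added after the data were seen were fits without dense-input regions (over 100 input reads per kb), a 1.5-fold threshold (glmTreat), and the overlap, score and union alternatives of the ATPneg comparisons. A region of H3K27ac or H3K4me1 was counted as dense if it overlapped a dense-input region of another target.

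Reads in regions were 4730905 and 5033230 (CTCF KO), 3880112 and 17055094 (CTCF WT), 3803369 and 3784506 (NIPBL KO), 17681215 and 16916106 (NIPBL WT), 7415143 and 7194434 (RAD21 KO), 24962590 and 21848632 (RAD21 WT), 4010016 and 4242112 (SMC3 KO), 17667209 and 15416715 (SMC3 WT), 30496715 and 28011360 (WAPL KO), 21488840 and 21978527 (WAPL WT), 23013317 and 21859316 (H3K27ac KO), 27183753 and 28358008 (H3K27ac WT), 16048349 and 16794584 (H3K4me1 KO) and 21829239 and 26637928 (H3K4me1 WT). Replicate CPM correlated at r = 0.945 and 0.618 for CTCF (KO and WT), 0.938 and 0.973 for NIPBL, 0.791 and 0.968 for RAD21, 0.931 and 0.908 for SMC3, 0.979 and 0.927 for WAPL, and 0.966 to 0.978 for the marks. The common dispersion was 0.000307 for H3K27ac and 0.000479 for H3K4me1, close to sampling noise, so splits of 1 library cannot be excluded, and these libraries were kept as 2 replicates. The fit was tested on simulated data in which a separate set of 100 regions was raised 2-fold for the camera test. Beside that set 200 regions were changed, 100 of them 2-fold and 100 4-fold. Of those, 0% and 0% were recovered for CTCF and RAD21, 38% and 90% for NIPBL, 0% and 15% for SMC3, 7% and 62% for WAPL, 53% and 94% for H3K27ac, and 68% and 98% for H3K4me1. Calls among unchanged regions were 18 of 91 for WAPL and 12 of 27 for SMC3. For every target but CTCF far fewer regions changed in the simulation than were called in the data. The simulated shares therefore do not carry over to those calls.

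The identity of the mark libraries was examined by 3 criteria in turn: a difference in correlation over 0.05, a ratio of reads near and 1 to 5 kb from transcription starts, and correlations over 8 subsets of shared regions (80% reciprocal overlap). Each was chosen after earlier values had been seen.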

Results

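The study mapped chromatin proteins by ChIP-seq in small pre-B cells, the bone marrow stage at which the Ig kappa light chain genes are rearranged, sorted from mice by flow cytometry. The cells were wild type (WT), knocked out for Brwd1 (KO), whose protein binds acetylated histones, or WT cells held for 2 hours in 126 nM oligomycin, an inhibitor of the mitochondrial ATP synthase (labelled ATPneg). The targets were the insulator protein CTCF, the cohesin subunits RAD21 and SMC3, the cohesin loader NIPBL, the cohesin release factor WAPL, and the histone marks H3K27ac and H3K4me1. Of the 40 samples, 36 were ChIP libraries, with 2 per target and condition, and 4 were inputs, with 2 per genotype. The ATPneg condition exists for NIPBL, RAD21, SMC3 and WAPL, and its libraries have peak lists but no deposited counts, so their depth is unknown. Reads within the regions of each target ran from 3784506 in a NIPBL KO library to 30496715 in a WAPL KO library. The KO libraries of NIPBL, RAD21 and SMC3 held 3784506 to 7415143 reads against 15416715 to 24962590 in their WT libraries. The labels do not say which part of Brwd1 is deleted, and ChIP reads over its DNA check no label. H3K4me1 upstream of Brwd1 (mm9, 16:96307693-96308289) held 3.12 and 4.47 normalized counts (CPM) in the KO libraries against 0.779 and 0.676 in WT.

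Whether the loss of BRWD1 changes cohesin was first read from SMC3, a core subunit of the cohesin ring. The SMC3 KO libraries held 4010016 and 4242112 reads and the WT libraries 17667209 and 15416715. Genotype thus cannot be told apart from a library difference that goes with depth. In the KO libraries SMC3 rose at short CTCF sites and fell over long regions away from them. At the promoter of the glycolysis gene Pgk1 (X:103382068-103382648) it rose from 3.94 ± 1.07 to 50.8 ± 1.39 CPM (SD, n = 2 per group), a log2 fold change of 3.69 ± 0.23 (SE, adjusted p = 0.000571). Near Klf2, a transcription factor gene that holds pre-B cells in quiescence (8:74889633-74890124), SMC3 rose from 2.24 ± 0.0681 to 31.6 ± 2.49 CPM (log2 3.81 ± 0.19, adjusted p = 0.000571). Near Bcl11a, needed for B lineage entry (11:23949200-23949636), it rose by 4.38 ± 0.23 on the log2 scale (adjusted p = 0.000571). The top of the ranked gains lay near the oxygen sensor gene Egln3 (12:55199798-55200208) (5.36 ± 0.35, 41.1-fold), then Pik3ap1 (5.28 ± 0.46), Fbxw7 (5.25 ± 0.29) and Sec13 (5.25 ± 0.31).

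Some of the named SMC3 gains lie beside genes of the pre-B stage, while the pre-B receptor list did not pass its test (camera, adjusted p = 0.301, 12 genes higher and 3 lower of 17). The region beside the surrogate light chain gene Igll1 gained 3.53 ± 0.48 (adjusted p = 0.00226), and that beside the recombinase gene Rag1 gained 3.33 ± 0.44 (adjusted p = 0.00208, and 0.0869 with input-subtracted counts). Vpreb2, a second surrogate light chain gene, gained 3.95 ± 0.27, and Plcg2, a kinase-activated lipase of the pre-B receptor, 3.38 ± 0.28. The Myc promoter (15:61814794-61815446) rose from 3.24 ± 0.776 to 26.8 ± 1.16 CPM (log2 3.05 ± 0.24, adjusted p = 0.000576). Regions within Brwd1 itself (3.53 ± 0.38, adjusted p = 0.00106), beside Gapdh (3.93 ± 0.26), Cox4i1 (4.17 ± 0.21), Atp5o (4.31 ± 0.29), Pim1 (4.22 ± 0.21) and Bcl2l1 (3.56 ± 0.21) also rose. So did regions near Tcf7 (4.55 ± 0.30), Cebpb (3.63 ± 0.15), Smarca5 (3.95 ± 0.30), Zfpm1 (3.95 ± 0.21), S1pr1 (3.69 ± 0.21) and Txnip (4.09 ± 0.28). In the Igk window, 3.02 ± 0.22 was gained near IgkJ1 and 4.86 ± 0.33 near Igkv17-121. All of these named gains overlap a WT CTCF peak. SMC3 fell at the promoter of the prefoldin gene Pfdn5 (15:102158125-102158245) from 24.1 ± 1.34 to 1.39 ± 0.277 CPM (17.2-fold, adjusted p = 0.000571), within Usp40 (−4.01 ± 0.39) and within Gpm6b (21.4-fold, adjusted p = 0.0332, WT 64.7 ± 73.4 CPM).

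Of 77109 SMC3 regions tested with edgeR, 17046 were higher and 13921 lower in KO. The higher regions had a median length of 282 bp and 69.1% overlapped a WT CTCF peak. The lower regions had a median length of 2113 bp, 0.237% overlapped a WT CTCF peak and 89.6% a WT RAD21 peak. Among the 12216 SMC3 regions at WT CTCF peaks 11778 rose and 33 fell, with a median log2 fold change of 3.62 against −0.44 elsewhere (camera, adjusted p = 2.17e-250). Among the 26651 regions at WT RAD21 peaks 541 rose and 12467 fell (adjusted p = 3.63e-38), and at WAPL peaks 2808 rose and 12498 fell (adjusted p = 1.19e-23). At H3K27ac peaks 3285 rose and 216 fell (adjusted p = 0.0457; 0.0501 with library totals, 0.106 without SMC3 WT 1, and adjusted p = 0.359 with an estimated correlation), and at NIPBL peaks the median was higher by 0.68 while the test leaned down (adjusted p = 0.735). The total of calls was 18709 without SMC3 KO 1 and 19408 without SMC3 KO 2, and Gpm6b lost its call without either (adjusted p = 0.25 and 0.195), as did Igll1 without KO 1 (0.0536). In simulated counts 15% of the regions changed 4-fold were recovered, and 12 of 27 calls lay among unchanged regions. Far fewer regions changed there than were called here, so neither share carries over to these calls.

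**Figure D1:**
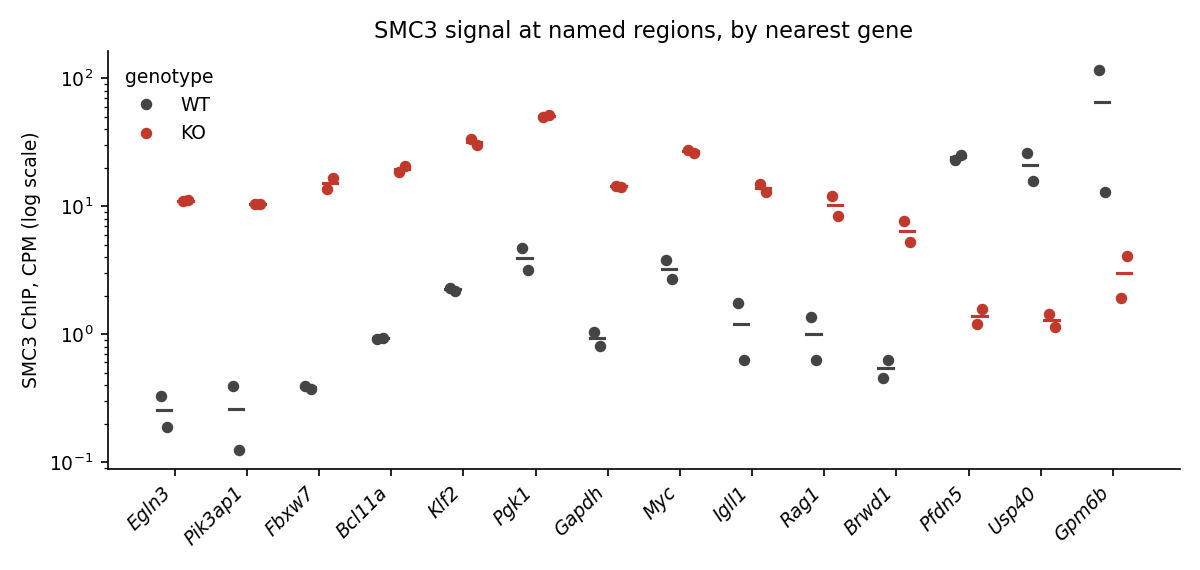
SMC3 ChIP signal (CPM, log scale) in the 2 WT and 2 KO libraries at regions named by their nearest gene, with points for libraries and lines for group means. The Klf2 region goes from 2.24 to 31.6 CPM and the Pfdn5 promoter from 24.1 to 1.39 CPM.

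RAD21, the kleisin that closes the ring, was compared in the same way. The named gains lie at WT CTCF peaks, but of all higher regions 6.35% do, against 11.8% of those not called. At H3K27ac peaks lie 92.4% of the higher regions, against 45.9% of those not called. Within Erg, a stem cell and early B transcription factor gene (16:95732269-95737089), RAD21 fell from 27.2 ± 0.575 to 6.85 ± 1.72 CPM (SD, n = 2 per group), a log2 change of −1.99 ± 0.28 (SE, adjusted p = 0.0433). A region upstream of Rag2, the partner of RAG1 in V(D)J recombination, fell by 1.62 ± 0.32 on the log2 scale. In the Igk window the region near Igkv3-12-1 changed by −1.93 ± 0.23, while that near Igkv2-95-1 (6:68618445-68618862), at a CTCF peak, rose from 1.40 ± 0.0864 to 9.49 ± 0.140 CPM (2.75 ± 0.26). RAD21 rose near Id3, an inhibitor of E proteins (2.70 ± 0.29), Adamts4 (3.96 ± 0.44), Hdhd2 (2.93 ± 0.55), Rmi2 (2.91 ± 0.32) and Ighv1-9 (2.89 ± 0.30), each at a WT CTCF peak. It changed by −4.60 ± 0.93 within Pigk, −3.57 ± 0.53 near Zfp648, −1.73 ± 0.27 near Tfrc and −1.93 ± 0.24 near Cd28. Regions near Mki67 (−1.58 ± 0.22), Mycn (−1.88 ± 0.26) and Pfkp (−1.99 ± 0.31) fell too.

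Of 84996 RAD21 regions tested, edgeR called 1954 higher and 17897 lower, a direction that turned with DESeq2 (11722 higher, 5289 lower) and without RAD21 KO 1 (23026 higher, 14262 lower). The lower regions had a median length of 1357 bp. Of them 83.7% overlapped a WT RAD21 peak, which is no separate evidence, since the regions pool the RAD21 lists themselves. Of the higher regions 94.5% had a dense input (over 100 reads per kb), against 52.2% of those not called. A rise at H3K27ac peaks was not tested apart from a rise at dense input. Among the 7812 regions at CTCF peaks 124 rose and 20 fell (median log2 1.81 against −0.88 elsewhere, camera adjusted p = 8.04e-18, but adjusted p = 0.478 with an estimated correlation). At NIPBL peaks 761 rose and 1252 fell, yet the test went up, with a median of 0.60 against −1.08 elsewhere (adjusted p = 2.29e-23). The test also went up at H3K27ac peaks, where 1806 rose and 56 fell (adjusted p = 1.25e-111), and down at WAPL peaks, where 998 rose and 14087 fell (adjusted p = 0.00155, but adjusted p = 0.364 with an estimated correlation). The KO libraries differed, with 51.9% of the peaks of RAD21 KO 1 and 2.11% of those of RAD21 KO 2 at a WT CTCF peak. Without RAD21 KO 1 the total was 37288 and the tests at CTCF and WAPL peaks lost their calls (adjusted p = 0.223 and 0.886), without RAD21 KO 2 it was 49148, and without RAD21 WT 1 or WT 2 edgeR called 0 (11920 and 4139 at an unadjusted p under 0.05). The edgeR total and the calls of these 16 named regions were also 0 with background scaling (36319 at an unadjusted p under 0.05), no filter (31754) or input-subtracted counts (17035), and the total without dense-input regions (5335), against 17011 calls by DESeq2.

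CTCF binding itself was compared to ask whether the insulator sites change with BRWD1. CTCF rose upstream of Cr2, a complement receptor gene of mature B cells (1:197067711-197068108), from 302 ± 211 to 730 ± 58.7 CPM (SD, n = 2 per group), a log2 change of 1.28 ± 0.27 (SE, adjusted p = 0.00964). It fell within Tcea3, an elongation factor gene, by 4.35 ± 0.88 on the log2 scale (adjusted p = 0.00374), within Ccdc162 by 1.78 ± 0.25 (adjusted p = 1.04e-08) and near Cxx1b by 3.89 ± 0.85 (adjusted p = 0.0138). Of 75717 regions 6 were higher and 24 lower, and 95.0% (exact 95% interval 94.7% to 95.3%) of the 16606 WT consensus CTCF peaks overlapped one of the 24471 KO consensus peaks, and between single libraries the share ran from 25.9% to 87.5%. A dense input was found in 66.7% of the higher and 91.7% of the lower regions, against 54.9% of those not called. At a WT CTCF peak lay 16.7% of the higher and 8.33% of the lower regions, against 21.7%. CTCF WT 2 listed 67796 peaks and CTCF WT 1 21429, and their CPM correlated across regions at r = 0.618 against 0.945 between the KO libraries. Over shared regions CTCF WT 2 correlated at r = 0.931 with SMC3 WT 2 and 0.813 with CTCF WT 1. It also correlated more with each KO and WT library of NIPBL, RAD21, SMC3 and WAPL than with CTCF WT 1. The measure thus singles out no target, and whether CTCF WT 2 holds CTCF stays open. The total of 30 calls became 66465 without CTCF WT 1, 17083 without CTCF WT 2, 11 without KO 1 and 9 without KO 2, and 0 with DESeq2 (8747 at an unadjusted p under 0.05), or in edgeR with library totals (9855) or background scaling (4402). In simulated counts 0 of 100 regions changed 4-fold were called.

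NIPBL loads cohesin onto DNA. In KO cells it fell near Foxo1, the transcription factor gene that drives Rag expression (3:52236201-52240778), from 22.4 ± 0.0432 to 13.3 ± 0.175 CPM (SD, n = 2 per group), a log2 change of −0.75 ± 0.16 (SE, adjusted p = 0.0477). It fell upstream of the chemokine receptor gene Cxcr4 by 2.30 ± 0.46 on the log2 scale (adjusted p = 0.0415) and near Osr1 by 1.47 ± 0.24 (adjusted p = 0.0202). NIPBL rose at the Pgk1 promoter by 1.45 ± 0.25 (adjusted p = 0.0270), upstream of Cr2 by 1.64 ± 0.16 (adjusted p = 0.00119), within the end-joining kinase gene Prkdc by 1.44 ± 0.27 and within Brwd1 by 1.48 ± 0.29 (adjusted p = 0.0391). The region within Chl1 (6:103599094-103599299) rose by 1.99 ± 0.07 (adjusted p = 2.42e-07), and those near Txndc11 by 1.95 ± 0.19 and Fbrs by 1.91 ± 0.31. Smaller gains lay within Erg (0.50 ± 0.07), near Hk1 (0.61 ± 0.09) and near Igkv13-57-2 (1.38 ± 0.21). Of 61586 regions 613 were higher and 388 lower, a direction that turned with library totals, at 464 and 6283. Of the higher regions 96.4% lay where the input was dense, over 100 reads per kb, against 70.5% of those not called and 28.9% of the lower regions. At H3K27ac peaks lay 79.3% of the higher regions, against 67.9% of those not called. Dense input and H3K27ac were not tested apart. At CTCF peaks 115 rose and 2 fell of 789 (camera, adjusted p = 1.14e-27), at RAD21 peaks 75 rose and 296 fell (8.49e-37), at WAPL peaks 360 rose and 350 fell while the test went down (1.50e-06, median −0.08 against 0.14 elsewhere), and at H3K27ac peaks 486 rose and 88 fell (8.97e-35). The total of 1001 calls was 166 without NIPBL KO 1 (4 lower), 78 without KO 2 (2 lower), 16 without WT 1 (0 lower) and 10 without WT 2 (0 lower), where 8, 10, 12 and 12 of the 13 named regions lost their calls. It was 0 in edgeR with input-subtracted counts (10278 at an unadjusted p under 0.05, DESeq2 711), where none of the named regions kept its call and the Erg region turned to −1.07.

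WAPL releases cohesin from DNA, and it was compared to see whether release changes with BRWD1. WAPL fell near Foxo1 (3:52234757-52240804) from 31.2 ± 0.377 to 9.47 ± 0.442 CPM (SD, n = 2 per group), a log2 change of −1.72 ± 0.11 (SE, adjusted p = 0.00142). It fell within Xrcc4, an end-joining gene (−1.61 ± 0.10), upstream of Rag2 (−1.57 ± 0.12), upstream of Cxcr4 (−1.69 ± 0.11), within Erg (−1.53 ± 0.11) and within its own gene Wapal (−1.62 ± 0.12). In the Igk window it fell near Igkv1-135 (−1.49 ± 0.12) and Il23r (−1.74 ± 0.12), and elsewhere near Cd28 (−1.63 ± 0.13), Pfkp (−1.64 ± 0.11) and Gatad2a (−2.56 ± 0.20). The Pfdn5 promoter went from 29.7 ± 0.949 to 0.467 ± 0.572 CPM (log2 −6.02 ± 0.64, adjusted p = 0.00313). WAPL rose within Tll1 (5.43 ± 0.40), at the Pgk1 promoter (1.35 ± 0.14) and near Ywhaz (1.49 ± 0.21). Of 126089 regions 16498 were higher and 34829 lower, a direction that turned with background scaling (50486 and 24440) and without dense-input regions (8909 and 3865). Of the higher regions 92.4% had a dense input, against 78.2% of those not called. At H3K27ac peaks lay 93.1% of the higher regions, against 77.6% of those not called. Dense input and H3K27ac were not tested apart. The lower regions had a median length of 736 bp and 68.8% overlapped a WT RAD21 peak. At WT RAD21 peaks 23972 of 28796 regions fell and 686 rose (median log2 −1.40 against 0.26 elsewhere, camera adjusted p = 6.90e-101). At CTCF peaks 450 rose and 28 fell (1.06e-16), at NIPBL peaks 4407 rose and 1610 fell (1.03e-07), and at H3K27ac peaks 15357 rose and 623 fell (7.17e-109). The total of 51327 was 3933 without WAPL KO 1 (81 higher, 3852 lower) and 4733 without KO 2 (209 higher, 4524 lower), where the Pgk1 (adjusted p = 0.0744 and 0.0576) and Ywhaz (0.0830 and 0.0783) regions lost their calls.

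**Figure D2:**
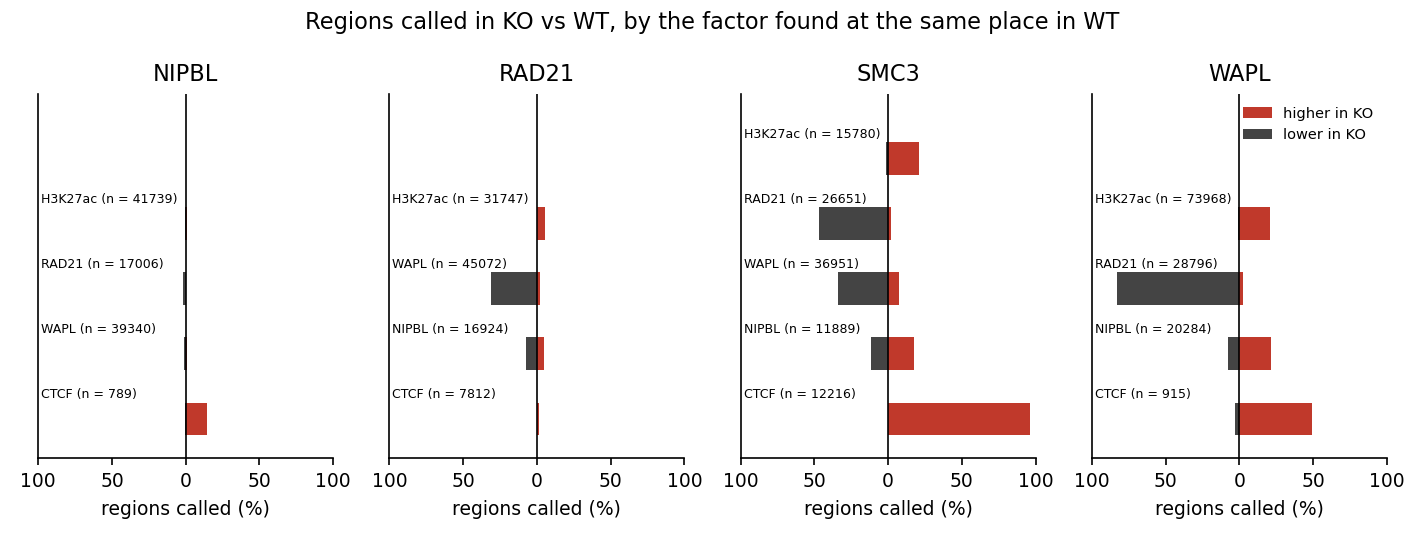
Percent of NIPBL, RAD21, SMC3 and WAPL regions called higher (right) or lower (left) in KO, by the factor with a WT peak at the same place, with the number of regions in each class. Of the 12216 SMC3 regions at CTCF peaks 11778 are higher, and of the 28796 WAPL regions at RAD21 peaks 23972 are lower.

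H3K4me1 marks enhancers, and the libraries labelled H3K4me1 were compared to see which enhancers and promoters change. The Syk promoter, a pre-B receptor kinase gene (13:52677866-52681108), fell from 38.2 ± 0.740 to 5.16 ± 0.509 CPM (SD, n = 2 per group), a log2 change of −2.88 ± 0.09 (SE, adjusted p = 6.07e-166). The promoter of Pou2af1, a coactivator gene of Oct factors in B cells (9:51021384-51024146), fell by 2.49 ± 0.10 on the log2 scale (adjusted p = 4.99e-110), and that of the NF-kB gene Rel by 2.26 ± 0.09. Promoters of Cxcr4 (−3.00 ± 0.09), Cd24a (−2.28 ± 0.12), Blnk (−1.13 ± 0.05), Pim1 (−2.04 ± 0.09), B2m (−3.77 ± 0.18), Ywhaz (−2.97 ± 0.10) and Hspa8 (−3.11 ± 0.15) fell too. Losses also lay within Smarca4, a chromatin remodeller gene (−1.71 ± 0.06), and at Sh3glb1 (−4.11 ± 0.14), Rbm39 (−4.00 ± 0.17), Zfpm1 (−1.29 ± 0.05) and Igll1 (−0.71 ± 0.20). H3K4me1 rose upstream of the Fc receptor gene Fcgr3 (1.65 ± 0.07), near Socs3 (1.94 ± 0.14), upstream of Brwd1 (2.32 ± 0.25) and at the promoters of Hic1 (2.86 ± 0.21) and Nxph4 (2.70 ± 0.17). Of 179582 regions 11573 were higher and 17921 lower, a direction that turned with library totals, at 16809 and 14208. Of the lower regions 32.0% were promoters and of the higher regions 14.1%, against 3.98% of those not called. Igll1 lost its call with DESeq2 (adjusted p = 0.305) and without H3K4me1 WT 1 (0.0876) or KO 2 (0.169). The peak names inside the H3K4me1 WT and H3K27ac KO lists belong to the other mark and the other genotype. The mark and the genotype of those libraries therefore stay unsettled, and the promoter losses cannot be told apart from an exchange of libraries. Whether the 2 replicates of a mark are separate samples or splits of 1 library is not settled either. The SE and p of both marks hold only if they are separate.

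H3K27ac marks active enhancers and promoters. In the libraries labelled H3K27ac it fell at Ighm, the mu heavy chain gene (12:114662215-114665333), from 65.2 ± 3.31 to 11.6 ± 0.415 CPM (SD, n = 2 per group), a log2 change of −2.49 ± 0.06 (SE, adjusted p = 5.42e-91). It fell at Ighj2, a heavy chain joining segment (−3.10 ± 0.22), within Runx1, a B lineage factor gene (−1.05 ± 0.05), and upstream of Mycn (−0.81 ± 0.04). It also fell at Hbp1 (−3.20 ± 0.31), Clk1 (−3.20 ± 0.31), Ywhaz (−2.37 ± 0.19) and Atf4 (−2.69 ± 0.32). It rose at the Pgk1 promoter (2.87 ± 0.14), at the promoters of the chaperone genes Fkbp5 (4.12 ± 0.30) and Hspa2 (4.03 ± 0.19), upstream of Fcgr3 (1.86 ± 0.10), near Myb (0.83 ± 0.07) and upstream of Brwd1 (2.49 ± 0.45). Of 235173 regions 13880 were higher and 24903 lower, a direction that turned with library totals (22208 and 15990) and with a 1.5-fold threshold (2657 and 1607). Of the lower regions 68.1% overlapped a dense-input region of another target, against 25.5% of the higher regions and 29.4% of those not called. The lower regions were longer (median 216 bp against 145 bp in the others), which favours such an overlap.

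The gene lists fixed beforehand asked whether groups of related genes move together, on counts summed per gene. For SMC3, the housekeeping list was higher (camera, adjusted p = 0.000240), with 13 genes higher and 0 lower of 14, and 14 higher when adjusted over the list alone; the call is lost at adjusted p = 0.820 with an estimated correlation. The oxidative phosphorylation list was also higher (adjusted p = 0.0449, but adjusted p = 0.820 with an estimated correlation), with 13 genes higher and 3 lower of 18. For H3K4me1 the list of cohesin, CTCF and BRWD1 genes was lower (5.80e-17, 2 higher and 15 lower of 21), as were B lineage transcription factors (2.54e-05, 5 and 17 of 25), pre-B receptor genes (0.000240, 2 and 14 of 23) and housekeeping genes (0.00116, 1 and 11 of 19). Each of these calls is lost at adjusted p = 0.820 with an estimated correlation. Adjusted over the list alone, those H3K4me1 counts were the same except for 3 higher pre-B receptor genes. The myeloid list was higher for H3K4me1 (0.00683, 10 and 2 of 24; adjusted p = 0.820 with an estimated correlation). The housekeeping list was higher for CTCF (0.00996, 0 of 16 genes called) and the late and mature B cell list for RAD21 (0.0449, 0 of 24 called), with adjusted p = 0.883 and 0.820 with an estimated correlation. For WAPL the Igk window was lower (0.0423, 20 regions higher and 81 lower of 178, or 22 and 89 adjusted over the list alone; adjusted p = 0.820 with an estimated correlation). In the other targets that window held 0 and 0 calls of 122 for CTCF, 1 and 0 of 66 for NIPBL, 1 and 35 of 160 for RAD21, 49 and 18 of 167 for SMC3, 26 and 18 of 242 for H3K27ac, and 16 and 37 of 205 for H3K4me1. No test passed for the T cell (smallest adjusted p = 0.128, H3K4me1), erythroid (0.555, CTCF), glycolysis (0.182, RAD21) or proliferation (0.182, SMC3) lists. With an estimated correlation 0 of the 10 list calls and 13 of the 16 class calls held. The oxidative phosphorylation call was lost without SMC3 WT 1 (0.138), WT 2 (0.105), KO 1 (0.120) or KO 2 (0.0855), the RAD21 call without WT 1 (0.139), WT 2 (0.0834), KO 1 (0.247) or KO 2 (0.0802), the WAPL call without WT 1 (0.144) or WT 2 (0.0828), and the CTCF call without WT 2 (0.182).

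The peak lists show how many sites each condition holds, and they are the measure that covers ATPneg cells. NIPBL lists held 40987 ± 21225 peaks in WT, 2190.5 ± 202 in KO and 12373 ± 3039 in ATPneg (mean ± SD, n = 2). The names inside the lists of NIPBL KO 2 (2048 peaks) and NIPBL WT 1 (25979) are of the other genotype, and by those names KO would hold 2333 and 25979 peaks and WT 2048 and 55995. WAPL lists held 78853 ± 3485 in WT, 60468 ± 11642 in KO and 3951.5 ± 950 in ATPneg. SMC3 lists held 52538.5 ± 16256 in WT, 12395 ± 102 in KO and 40052 ± 870 in ATPneg, and RAD21 lists 45088.5 ± 3770, 27497.5 ± 15860 and 26079.5 ± 13724. CTCF lists held 44612.5 ± 32786 in WT and 27154 ± 1335 in KO, H3K27ac lists 202685.5 ± 70.0 and 154054 ± 734, and H3K4me1 lists 136032.5 ± 5728 and 132658 ± 2391. The 2 groups did not overlap except for CTCF (exact permutation p = 1) and H3K4me1 (0.667), and 0.333 is the smallest p an exact two-sided permutation test of 2 against 2 can give. With the stricter score the ratio to WT turned from 0.767 to 1.1 for WAPL KO and from 0.762 to 1.12 for SMC3 ATPneg, and moved from 0.578 to 0.947 for RAD21 ATPneg and from 0.0534 to 0.0809 for NIPBL KO. SMC3 peaks covered 47.7 Mb in WT, 3.69 Mb in KO and 18.8 Mb in ATPneg. Leaving out 1 library moved the KO to WT ratio from 0.609 to 0.401 (CTCF WT 1) or 1.27 (CTCF WT 2), from 0.610 to 0.361 (RAD21 KO 2) and from 0.0534 to 0.0843 (NIPBL WT 2), and the ATPneg to WT ratio from 0.302 to 0.476 (NIPBL WT 2) and from 0.578 to 0.363 (RAD21 ATPneg 2).

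**Figure D3:**
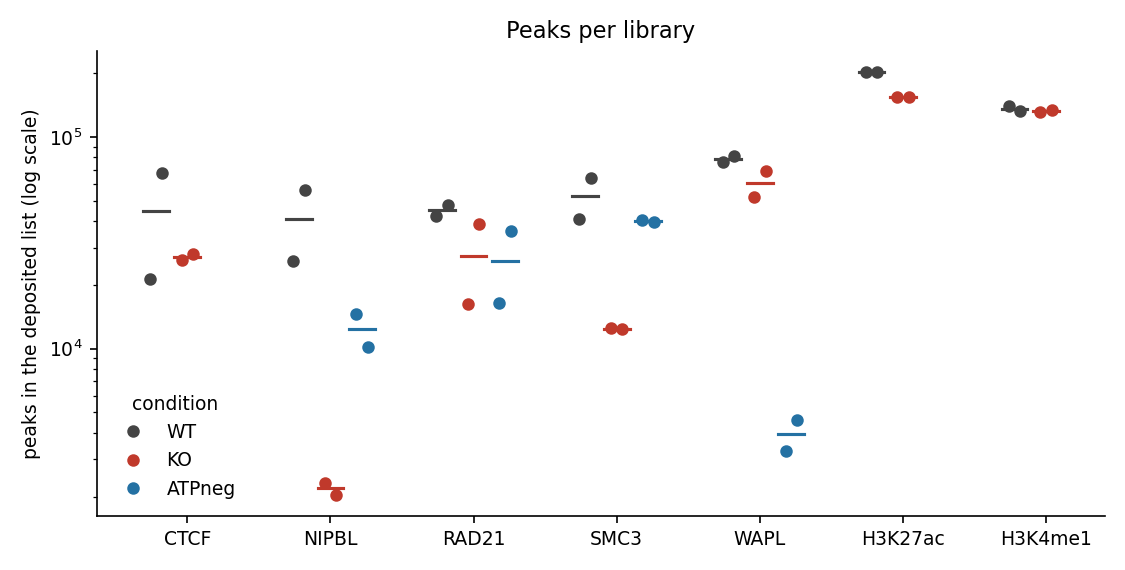
Peaks in the deposited list of each library (log scale) by target, with points for libraries and lines for means of the 2 libraries per condition. WAPL lists go from 78853 in WT to 3951.5 in ATPneg, and NIPBL lists from 40987 in WT to 2190.5 in KO.

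Where those peaks lie was set against the 16606 CTCF consensus peaks of WT cells. Of SMC3 peaks 1.48% ± 0.178 (SD, n = 2) lay at a CTCF peak in WT, 81.9% ± 0.622 in KO and 38.6% ± 0.584 in ATPneg. RAD21 peaks lay there at 1.45% ± 0.0495 in WT, 51.9% and 2.11% in the KO libraries and 42.1% ± 1.45 in ATPneg. For NIPBL the shares were 1.76% ± 0.625, 20.5% ± 5.53 and 4.70% ± 1.12, and for WAPL 0.902% ± 0.0623, 1.31% ± 0.142 and 16.2% ± 4.23. Cohesin sites, where SMC3 and RAD21 consensus peaks overlap, numbered 26179 in WT, 677 in KO and 8145 in ATPneg. WAPL covered 89.1% of the WT sites (exact 95% interval 88.7% to 89.5%), NIPBL 12.0% and CTCF 1.44% (1.30% to 1.60%). Of the KO sites 35.3% (31.7% to 39.0%) lay at KO CTCF peaks, 55.5% at WT CTCF peaks, 57.8% at NIPBL and 54.5% at WAPL peaks. Of the ATPneg sites 80.3% (79.5% to 81.2%) lay at WT CTCF peaks, 15.8% at NIPBL and 13.0% at WAPL peaks. With the union of both replicates the CTCF shares were 23.5% in WT, 79.7% in KO and 53.6% in ATPneg and the NIPBL shares 38.8% in WT and 18.3% in KO, with 23.3% of the KO sites at WAPL, and with the stricter score the KO shares were 9.79% at CTCF and 78.0% at NIPBL. Without RAD21 KO 2 the KO shares were 93.5% at CTCF, 5.77% at NIPBL and 6.04% at WAPL, and without SMC3 KO 2 21.8% lay at CTCF. Without RAD21 ATPneg 1 the ATPneg shares were 6.65% at NIPBL and 4.98% at WAPL, and without RAD21 ATPneg 2 25.6% lay at NIPBL.

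**Figure D4:**
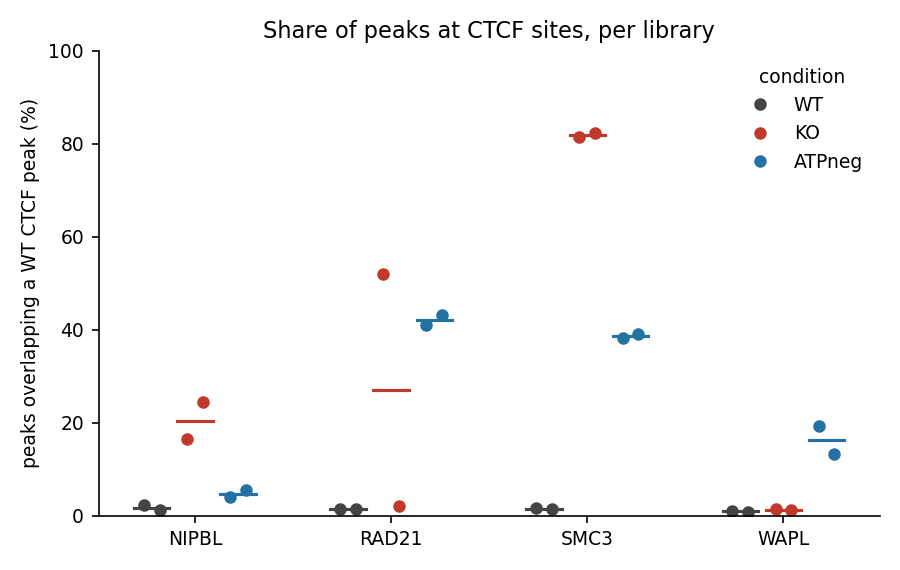
Percent of the peaks of each library that overlap a WT CTCF consensus peak, for the 4 targets with ATPneg libraries, with points for libraries and lines for means of 2. SMC3 goes from 1.48% in WT to 81.9% in KO and 38.6% in ATPneg, and the 2 RAD21 KO libraries lie at 51.9% and 2.11%.

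ATPneg cells were compared with WT and with KO cells to ask whether blocking ATP synthesis moves the same sites as losing BRWD1. Of the 33564 SMC3 consensus peaks of WT cells 6.41% (exact 95% interval 6.15% to 6.68%) overlapped one of the 31482 ATPneg peaks, against 1.40% after a shift of 1 Mb. Of the 9377 SMC3 peaks of KO cells 95.9% (95.4% to 96.3%) overlapped an ATPneg peak. NIPBL kept 29.4% of 20548 WT peaks in ATPneg cells, and 89.9% of its 1125 KO peaks overlapped an ATPneg peak. WAPL kept 3.56% of 57889 WT peaks, and 4.32% of its 45322 KO peaks overlapped an ATPneg peak. RAD21 kept 2.50% of 35434 WT peaks, and 22.7% of its 7027 KO peaks overlapped an ATPneg peak. A short ATPneg list limits such shares, and WAPL had 2183 ATPneg consensus peaks. In the other direction 94.8% of the WAPL ATPneg peaks overlapped a WT peak and 89.8% a KO peak. These shares were 74.2% and 12.4% for NIPBL, 6.84% and 28.2% for SMC3, and 9.39% and 16.9% for RAD21. The WT peaks found in both KO and ATPneg lists numbered 278 for SMC3 against 22.2 if independent (a ratio of 12.5), 496 against 30.8 for RAD21 (16.1), 712 against 219 for NIPBL (3.25) and 1933 against 807 for WAPL (2.39). Both lists were set against the same WT libraries, and how much of that excess comes from the shared controls was not measured. With the union of both replicates the shares of WT and KO peaks were 6.02% and 38.9% for RAD21, 6.51% and 8.29% for WAPL and 9.85% of WT peaks for SMC3, and with the stricter score 10.8% and 5.42% of WT peaks for SMC3 and WAPL, with an SMC3 ratio of 6.92. Without NIPBL WT 1 the NIPBL share was 13.9% and its ratio 6.82, without WAPL ATPneg 1 the WAPL shares were 7.13% and 8.69%, without RAD21 WT 1 the RAD21 ratio was 10.6, and without RAD21 ATPneg 2 the RAD21 shares were 4.1% and 57.3% (KO share 4.73% without RAD21 KO 1 and 39.2% without KO 2).

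Input DNA, sequenced without an antibody, gives the background signal of the regions in each genotype. There is 1 input column per genotype, so these values have no replicates and no test. At 20 reads over both columns counting noise alone can pass 2-fold, and its part in these numbers was not measured. Of the SMC3 regions with at least 20 input reads 1922 of 49065 (3.92%) differed over 2-fold between KO and WT input, with 1121 higher and 801 lower, or 2947 higher and 246 lower when scaled by library totals. The numbers were 2168 of 66709 (3.25%) over CTCF regions, 1495 of 54851 (2.73%) over NIPBL regions, 1926 of 61782 (3.12%) over RAD21 regions and 3223 of 98738 (3.26%) over WAPL regions.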

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

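The tests without dense-input regions, with a 1.5-fold threshold, and with other overlaps, scores or unions in the ATPneg comparisons were chosen after the result was seen; the others were planned. Of the results that answer a comparison 116 alternative values moved beyond their spread or by over 1.5 times and 225 did not, and of the values for named regions and sets 1249 kept their direction and side of the threshold, 275 lost the call, 6 gained one and 3 changed direction. With 2 libraries per group each left-out library leaves a lone library that is assumed to vary like the others. Except where a sentence names one, the cause was not tested.

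Scaling: with library totals edgeR called 0 CTCF regions (9855 at an unadjusted p under 0.05) and 6747 for NIPBL (464 higher, 6283 lower). With background scaling it called 0 for CTCF (4402 at an unadjusted p under 0.05), 0 for RAD21 (36319) and 3877 for NIPBL (3369 higher, 508 lower), against 711 by DESeq2 for NIPBL and 17011 for RAD21. Splits also moved for SMC3 with background scaling (21342 higher, 7483 lower), for WAPL with library totals (27669 and 31674) and background scaling (50486 and 24440), for H3K27ac with library totals (22208 and 15990) and background scaling (7418 and 50099), and for H3K4me1 with library totals (16809 and 14208) and background scaling (8414 and 23695). DESeq2 called 0 for CTCF (8747 at an unadjusted p under 0.05; edgeR 30), 25138 for WAPL, 12351 for H3K27ac (2560 higher, 9791 lower) and 10916 for H3K4me1 (2853 higher, 8063 lower), and its split was 560 and 151 for NIPBL and 11722 and 5289 for RAD21. The median log2 fold change shifted by 0.12 (CTCF), −0.24 (NIPBL), 0.13 (SMC3), 0.18 (WAPL) and 0.11 (H3K27ac) with library totals. With background scaling it shifted by 0.42 (CTCF), 0.16 (NIPBL), 0.82 (RAD21), 0.40 (SMC3), 0.48 (WAPL) and −0.19 (H3K27ac), and with DESeq2 by 0.37 (CTCF), 0.46 (RAD21) and 0.13 (SMC3).

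Counting: without the filter edgeR called 5 CTCF regions and 0 for RAD21 (31754 at an unadjusted p under 0.05; DESeq2 17011). With input-subtracted counts it called 0 for CTCF (5684), 0 for NIPBL (10278; DESeq2 711) and 0 for RAD21 (17035), 20055 for SMC3 and 26754 for WAPL, and the NIPBL region within Erg went from 0.50 to −1.07 (adjusted p = 0.790). Without dense-input regions it called 0 for CTCF (2891 at an unadjusted p under 0.05), 160 for NIPBL (156 higher, 4 lower), 0 for RAD21 (5335), 18545 for SMC3, 12774 for WAPL (8909 higher, 3865 lower), 16857 for H3K27ac and 18505 for H3K4me1; fewer regions are tested there. With a 1.5-fold threshold it called 1 for CTCF, 40 for NIPBL, 0 for RAD21 (31517 at an unadjusted p under 0.05), 25180 for WAPL, 4264 for H3K27ac (2657 higher, 1607 lower) and 8524 for H3K4me1.

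Replicate block: the labels do not pair the libraries, and after removal of group means the pairs correlated at r = −0.21 for CTCF and −0.06 to 0.03 for the others. With the replicate number as a block edgeR called 3 regions for CTCF, 7027 for NIPBL (3286 higher, 3741 lower), 0 for RAD21 (31820 at an unadjusted p under 0.05; DESeq2 17011), 29093 for SMC3, 44464 for WAPL, 40062 for H3K27ac and 30011 for H3K4me1. The input comparison has 1 column per genotype, so no block could be fitted.

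Left-out libraries: the calls ran from 9 (without CTCF KO 2) to 66465 (without WT 1) for CTCF, from 10 (without WT 2) to 166 (without KO 1) for NIPBL (at most 4 of them lower), and from 0 (without WT 1 or WT 2; 11920 and 4139 at an unadjusted p under 0.05 in edgeR, DESeq2 17011 with all libraries) to 49148 (without KO 2) for RAD21. RAD21 turned direction without KO 1 (23026 higher, 14262 lower). The calls ran from 18709 (without KO 1) to 40745 (without WT 2) for SMC3 and from 3933 (without KO 1; 81 higher) to 65246 (without WT 1) for WAPL, and stayed within 1.5 times for both marks. The test of RAD21 at CTCF peaks gave adjusted p = 2.10e-108 to 0.223 and that at WAPL peaks 5.83e-13 to 0.886, both turning direction without RAD21 KO 1.

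Named regions: of the 13 for NIPBL, 8 lost their calls without KO 1, 10 without KO 2, 12 without WT 1 and 12 without WT 2. SMC3 at Igll1 lost its call without KO 1 (adjusted p = 0.0536), at Rag1 with subtracted counts (0.0869) and at Gpm6b with subtracted counts (0.0945), without KO 1 (0.25), without KO 2 (0.195) or without dense-input regions (0.0774). WAPL lost its calls at Pgk1 (0.0744 and 0.0576) and Ywhaz (0.0830 and 0.0783) without KO 1 or KO 2, and at Igkv1-135 without dense-input regions (0.0703). H3K4me1 at Igll1 lost its call with DESeq2 (0.305), without WT 1 (0.0876), without KO 2 (0.169) and with the 1.5-fold threshold (adjusted p = 1).

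Sets: camera with an estimated correlation called 0 of the 84 list tests (10 with the preset value) and 13 of 17 class tests (16). Within 10 kb of a gene the housekeeping list for CTCF (adjusted p = 0.177), the late and mature B cell list for RAD21 (0.333), the oxidative phosphorylation list for SMC3 (0.0620) and the Igk window for WAPL (0.117) lost their calls, and the Igk window for H3K4me1 gained one (0.0174). With library totals RAD21 lost the late and mature B cell call (0.0985). Calls were gained with background scaling by proliferation genes for SMC3 (0.0480) and B lineage transcription factors for H3K27ac (0.0286), without NIPBL KO 1 by pre-B genes for NIPBL (0.0376), without RAD21 KO 2 by housekeeping genes for RAD21 (0.0418), and without SMC3 WT 2 by proliferation genes for SMC3 (0.0449).

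Peaks per library: with the stricter score the ratio to WT was 0.0809 for NIPBL KO, 0.947 for RAD21 ATPneg, 0.301 for SMC3 KO, 1.12 for SMC3 ATPneg, 1.1 for WAPL KO, 0.0682 for WAPL ATPneg and 0.893 for H3K4me1 KO. With 1 library left out it was 0.401 (without CTCF WT 1) to 1.27 (without WT 2) for CTCF KO, 0.0391 (without NIPBL WT 1) to 0.0843 (without WT 2) for NIPBL KO and 0.221 to 0.476 for NIPBL ATPneg, and 0.194 (without SMC3 WT 1) to 0.302 (without WT 2) for SMC3 KO and 0.625 to 0.976 for SMC3 ATPneg.

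Cohesin sites: with the union of both replicates the shares were 23.5% at CTCF, 38.8% at NIPBL and 90.3% at WAPL in WT, 79.7% at CTCF, 18.3% at NIPBL and 23.3% at WAPL in KO, and 53.6% at WT CTCF peaks in ATPneg. With the stricter score they were 2.10% at CTCF and 84.9% at WAPL in WT, and 9.79% at CTCF and 78.0% at NIPBL in KO. With 1 library left out the WT shares were 1.17% to 1.71% at CTCF, 10.3% to 14.9% at NIPBL and 81.0% to 88.5% at WAPL. The KO shares were 21.8% (without SMC3 KO 2) to 93.5% (without RAD21 KO 2) at CTCF, 5.77% (without RAD21 KO 2) to 54.4% at NIPBL and 6.04% (without RAD21 KO 2) to 67.5% at WAPL. The ATPneg shares were 4.98% (without RAD21 ATPneg 1) to 15.5% at WAPL and 57.8% to 79.6% at WT CTCF peaks.

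ATPneg comparisons: the share of WT peaks found in ATPneg was 6.02% (RAD21), 9.85% (SMC3) and 6.51% (WAPL) with the union, and 10.8% (SMC3) and 5.42% (WAPL) with the stricter score. The share of KO peaks found in ATPneg was 87.1% (NIPBL), 38.9% (RAD21) and 8.29% (WAPL) with the union and 95.1% (SMC3) with the stricter score. With 1 library left out the WT shares were 13.9% (without NIPBL WT 1) to 43.7% for NIPBL, 2.55% to 4.1% (without RAD21 ATPneg 2) for RAD21, 5.77% to 8.16% for SMC3 and 2.54% to 7.13% (without WAPL ATPneg 1) for WAPL. The KO shares were 78.3% to 92.3% for NIPBL, 4.73% (without RAD21 KO 1) to 57.3% (without ATPneg 2) for RAD21, 92.1% to 97.0% for SMC3 and 3.0% to 8.69% (without WAPL ATPneg 1) for WAPL. The excess over independence was 6.92 for SMC3 and 1.79 for WAPL with the stricter score, and with 1 library left out 13.1 to 14.2 for SMC3, 2.61 to 2.78 for WAPL, 4.06 to 6.82 (without NIPBL WT 1) for NIPBL and 10.6 (without RAD21 WT 1) to 14.7 for RAD21. The deposited count tables hold no ATPneg columns, so the scaling, DESeq2, filter, subtraction and block alternatives were not run there. Scaled by library totals, 2904 RAD21 regions (2644 higher, 260 lower) and 3193 SMC3 regions (2947 higher, 246 lower) differed over 2-fold in input.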

Other observations

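Of the tests below, those of dense input, of a swap between RAD21 libraries and of the mark identities were chosen only after the result was seen; those of depth, of list length and of CTCF WT 2 were planned.

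The SMC3 gains and losses lie in different places. Of the regions with higher SMC3 in KO 1.88% lay on the X chromosome, 7.57% had no gene within 200 kb and 10.5% were promoters. For lower SMC3 the shares were 9.53%, 38.5% and 0.661%, and for SMC3 regions not called 7.28%, 34.5% and 1.65%. On the X chromosome lay 9.39% of the lower RAD21 regions (5.79% of those not called), 9.25% of the lower WAPL regions (4.97%) and 11.1% of the lower NIPBL regions (5.84%). These differences were not tested.

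Some places changed for several targets. The promoter of Pgk1, a glycolysis gene on the X chromosome, rose 12.9-fold for SMC3 (adjusted p = 0.000571), 2.74-fold for NIPBL (0.0270), 2.55-fold for WAPL (0.00326) and 7.33-fold for H3K27ac (5.87e-48). The Pfdn5 promoter fell 17.2-fold for SMC3 and 64.7-fold for WAPL. Upstream of Fcgr3, an Fc receptor gene, H3K27ac rose 3.63-fold and H3K4me1 3.14-fold. A region within Erg fell 3.97-fold for RAD21 and 2.89-fold for WAPL. The NIPBL call at Pgk1 ended with input-subtracted counts (adjusted p = 0.212) and without NIPBL KO 1 (0.210), KO 2 (0.105), WT 1 (0.20) or WT 2 (0.251). The WAPL calls at Pgk1 ended without WAPL KO 1 (adjusted p = 0.0744) or KO 2 (0.0576), and the RAD21 calls at Erg without either WT library, where edgeR called 0 RAD21 regions (11920 and 4139 at an unadjusted p under 0.05, DESeq2 17011 with all libraries).

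The KO lists of NIPBL, SMC3 and RAD21 are shorter than the WT lists, and their libraries are shallower. After the WT counts were thinned to the KO background depth, WT libraries still held 5.04 times (3.61 to 7.08 over pairs of libraries) as many detected regions for NIPBL. For SMC3 the ratio was 2.55 (2.27 to 2.85), and both exceed 1.5, a bound chosen beforehand. The merged regions pool the libraries of a target, whose WT lists are longer. Such a count favours WT, so depth is not excluded. For RAD21 the ratio was 1.36 (1.03 to 1.98), on both sides of the bound, so depth and a loss of RAD21 cannot be told apart there either. In the count tests with TMM factors 613 NIPBL regions were higher and 388 lower (3369 and 508 with background scaling, 560 and 151 with DESeq2, 464 and 6283 with library totals), for SMC3 17046 and 13921 (21342 and 7483 with background scaling, 18355 and 10244 with DESeq2), and for RAD21 1954 and 17897 (11722 and 5289 with DESeq2). A loss of sites without BRWD1 thus stays open for all 3 targets; for NIPBL an exchange of 2 lists by their names was not tested, and the reads of the columns (3803369 and 3784506 in KO, 17681215 and 16916106 in WT) go with the titles.

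SMC3 peaks sit at CTCF peaks in KO and ATPneg cells and hardly in WT cells. Dilution by long WT lists is argued against by the 5000 highest-scoring SMC3 WT peaks, of which 5.75% lie at a CTCF peak (KO 92.0%, ATPneg 96.4%), and dense input by the lower SMC3 regions, of which 5.01% have one. A swap between RAD21 KO 2 and a RAD21 WT library would need a WT list at CTCF peaks, and the highest such share is 1.49%. Over shared regions RAD21 KO 2 correlated more with CTCF WT 2 (r = 0.889) than with its best RAD21 library (0.854). The same held for NIPBL WT 2 (0.911 against 0.879) and WAPL KO 2 (0.930 against 0.914). Libraries of the marks, SMC3 KO and CTCF KO correlated less. The label of RAD21 KO 2 thus stays open. Whether CTCF WT 2 holds another target stays open. It correlated at r = 0.931 with SMC3 WT 2 and 0.813 with CTCF WT 1 over the same regions (difference 0.118, the highest over 24 libraries). But it correlated more with each KO and WT library of NIPBL, RAD21, SMC3 and WAPL than with CTCF WT 1. For NIPBL WT 1 the values were 0.975 against 0.941, so the measure singles out no target. CTCF WT 2 holds 77.5% of the CTCF WT 1 peaks, against 4.38% in SMC3 WT 2 and 85.0% in SMC3 ATPneg 1. Of the CTCF WT 1 peaks alone, 3.19% and 4.38% were found in the SMC3 WT lists, against 50.2% and 50.4% in the KO lists. RAD21 KO 1 held 41.3% of them and RAD21 KO 2 4.17%. A move of cohesin from long regions to CTCF sites without BRWD1 may be the cause, but it was not tested, and RAD21 KO 2 goes against it. Lower regions of NIPBL, SMC3 and WAPL mostly lay at WT RAD21 peaks (76.3%, 89.6% and 68.8%), against 27.5%, 29.6% and 5.53% of those not called. A difference in enrichment between WT and KO libraries was not tested either. Libraries labelled with the same genotype can differ in their share at CTCF peaks too. Of the 5000 highest-scoring peaks of CTCF WT 1 (3880112 reads) 99.5% lay at a CTCF consensus peak. For CTCF WT 2 (17055094 reads), whose target stays open, the share was 47.4%. The consensus was made from these same lists.

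The peak names in the H3K4me1 WT lists are those of the H3K27ac KO samples. The names in the H3K27ac KO lists are those of the H3K4me1 WT samples. It cannot be told apart from the counts whether the libraries or only the names are exchanged. With exchanged libraries the H3K4me1 comparison would set KO against KO and the H3K27ac comparison WT against WT. Over shared regions H3K4me1 WT correlated with H3K27ac WT more than with H3K4me1 KO by 0.00748 (−0.0191 to 0.269 over 8 subsets of regions, over 0.05 in 1), and H3K27ac KO with H3K4me1 KO more than with H3K27ac WT by −0.00217 (−0.0126 to 0.137, over 0.05 in 1). A ratio of reads at and around transcription starts placed them at −5.21 and 0.00686 on a scale from their own mark (0) to the other (1). It came from 128 starts where 500 were needed, so it decides nothing. Over 3197 regions at starts without dense input, H3K4me1 WT held 2.92% ± 0.0286 of its reads (SD, n = 2), against 1.29% ± 0.00726 in H3K4me1 KO. Over 711 such regions H3K27ac WT held 0.143% and H3K27ac KO 0.114%. The regions of the marks differ, so these shares do not place the libraries either. An exchange could change every mark value in the report, and no biological explanation was tested.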
